A study of Mus musculus with 12 samples.

How the data were processed

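RNA was measured in brain endothelial cells, the cells that line the brain's blood vessels, taken from wild-type C57BL/6 mice of 2 ages: 19 months (old, 6 samples) and 3 months (young, 6 samples). Per the labels' protocols, cortex and hippocampus of 2 mice were pooled for each sample and dissociated, endothelial cells were sorted by flow cytometry, cDNA was made with SMART-seq v4 and libraries with Nextera XT. The submitters' processing notes name FastQC 0.11.2, STAR 2.4.2a, Cuffdiff 2.2.1, R 3.2.2 and the genome build mm9, without saying what each was used for. The counting tool and the gene annotation are not given in the sources used here.

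The authors deposited a single table of 24015 gene symbols by 12 samples, whose values are a signal per gene that its name calls normalized counts. In the deposited table every column is made of whole multiples of its smallest value above 0, so each column is a whole read count per gene divided by a single size factor. After division by that step, 100% of the values were whole within 0.001. The size factors read from the steps equalled median-of-ratios factors recomputed from the recovered reads in 12 of 12 samples (within 1e-06), a match found from the values and not stated in the labels. Recovered reads in genes ran from 25809499 to 40393814 per sample, and 6951 of the symbols were 0 in every sample. Reads carry no molecular identifiers, so counting intervals cover counting error only.

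The values were put on the scale log2(value + 1). Genes with a mean of at least 10 over the 12 samples were kept, which left 12777. Old and young were compared with limma 3.58.1 in R 4.3.3 (linear model with age as its only term, moderated variances with a mean-variance trend), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Every adjusted p printed for a gene is from this fit unless another tool is named. A fold on this scale is a difference of mean logs, which for genes with low values or with some samples near 0 can lie above or below the ratio of the group means. As a count-based alternative, the recovered reads were tested with edgeR 4.0.16 (quasi-likelihood, TMM factors, its own low-count filter, 12580 genes) and with DESeq2 1.42.0. Differences of single quantities between ages were tested with two-sided exact permutation tests over the 924 ways to label 6 of 12 samples, whose smallest possible p is 0.00216.

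Before the data were examined, 40 gene lists were fixed: 26 for themes of endothelial biology and 14 of markers of other cell types. Of their 996 entries, 978 matched the table, older symbols included. Lists with at least 5 tested members, 35 in all, were tested as 1 family with camera (preset inter-gene correlation 0.01), which compares a list's members with all other genes, again with an estimated correlation, and with fry. For each list the number of members past the threshold is given over all genes tested and adjusted over the list alone. Lists share some genes, and the brain endothelium itself expresses several genes of the lists for other cell types, such as Clu and Gja1 of the astrocyte list. The genes named were chosen by a rule fixed at the same time: Vcam1, the gene of the series title; the 10 largest rises and 10 largest falls among genes past the threshold with at least 5 of 6 old samples beyond the young median; and for each list up to 3 members past the threshold with the smallest p, or the member with the smallest p where none passed. The rule gave 86 genes, some of which are not reported here. Any other gene named was chosen after its values were seen, and is said to be.

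The test was tried on simulated reads with known changes, drawn for the same genes and library sizes. Changes were planted only in genes above a minimum mean level, and each gene was drawn independently of the others. The recovery rates therefore do not cover genes of lowest level, where many of the largest folds below were found. For the comparison of old with young, limma on 12490 simulated genes recovered 80% of the genes changed by 1 on the log2 scale and 94% of those changed by 2, with 4.69% of its calls false. On the same kind of simulated reads edgeR recovered 81% and 95% (2.62% of calls false), DESeq2 87% and 98% (14.3% of calls false), and an exact Wilcoxon test recovered 0% of either.

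No 2 samples of an age agreed within sampling noise: the lowest chi-square per degree of freedom between their reads was 34.0, over genes with at least 20 reads. The labels do not say whether the pools came from different animals, so p-values measure the spread between these samples. Other choices tried were the pseudocount, the filter, the scaling, the variance model, sample weights, the title number as a block, other tests, a fold threshold, marker scores as covariates and each sample left out in turn. Settings added after seeing the data were a term for, or removal of, 3 samples (old 7, old 9 and young 9) whose values fell with transcript GC content. Their slopes over 8580 well measured genes were at most -0.12 on the log2 scale per 10 percentage points, against at least -0.01 in the other 9 samples. This set and the limit of -0.1 behind it were chosen with the data in view, and over all tested genes the same limit picks 2 samples (old 9 and young 9), which were run as well. Removal of a GC and length trend and the astrocyte score as a covariate were also added then. GC content and length came from the longest transcript per symbol in GENCODE M21, which covered 95.5% of tested genes. That annotation is of a different build from the authors' mm9, so no coordinates are given.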

Results

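The data are RNA-seq profiles of sorted brain endothelial cells from cortex and hippocampus, 6 samples from old mice (19 months) and 6 from young mice (3 months), with 25809499 to 40393814 reads in genes per sample. Correlations between samples of the same age lay between 0.911 and 0.963 on the log2 scale. The first principal component held 27.4% of the variance and differed between the ages (exact permutation p = 0.00433, adjusted p = 0.026 over 6 sample measures), although young 9, at 17.7, lay among the old samples, which ran from 4.28 to 69.0. The design implies a single comparison: how the endothelial transcriptome differed between old and young mice. The series title points within it to VCAM1, an adhesion molecule on endothelial cells that binds leukocytes.

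Vcam1 RNA did not differ measurably between the ages. Its normalized count was 5606 ± 1101 in old and 5763 ± 1098 in young samples (SD, n = 6 each), a fold of 0.97 with a 95% confidence interval of 0.79 to 1.20 (limma, adjusted p = 0.89; exact permutation p = 0.768). The read depth at these levels did not limit the comparison, and the interval leaves out a rise beyond 1.20-fold in the average of the sorted cells. A change in a small fraction of vessels, or in VCAM1 protein, was not analysed here. Of 36 alternative settings, 0 took Vcam1 past the threshold. Icam1, a related leukocyte adhesion molecule, was lower in old samples (2123 ± 552 against 3935 ± 1247, log2 fold -0.87, adjusted p = 0.0199). Among the 19 tested genes of the leukocyte adhesion list, 0 rose and 1 fell (Icam1), or 1 rose and 2 fell adjusted over the list alone, and the list as a whole did not pass (camera adjusted p = 0.399).

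**Figure D1:**
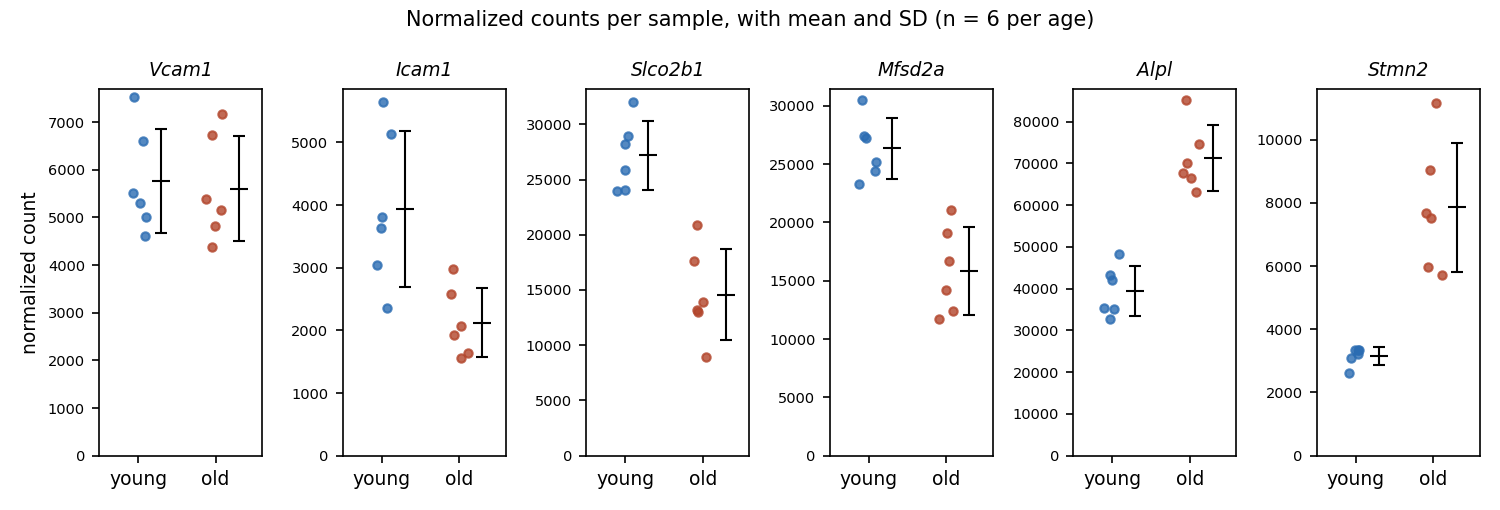
Normalized counts (vertical axes, each from 0) of 6 genes in the 6 young and 6 old samples, 1 point per sample, with the mean and SD beside them. Vcam1 overlapped between the ages, at 5763 in young and 5606 in old samples on average, while every old sample lay below every young sample for Slco2b1 and Mfsd2a and above for Alpl and Stmn2.

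Across the transcriptome, 887 of 12777 genes passed the threshold, 477 of them higher and 410 lower in old samples. At least a 2-fold change was seen in 350 of these (250 higher, 100 lower), and the median absolute log2 fold of the genes past the threshold was 0.84. Old and young samples did not overlap at all for 548 genes, 4.29% of those tested, where chance gives 0.216%. An unadjusted p under 0.05 was found for 3043 of the 12777 genes, which is the background for such counts in the lists below. In each of the 72 genes given by the naming rule that passed, 6 of 6 old samples lay beyond the young median in the direction given, which the choice of these genes by p and fold favours and which adds no evidence. On the recovered reads edgeR called 761 genes (437 higher, 324 lower), 738 of them shared with limma in the same direction. DESeq2 called 1408, and 554 genes passed without young 4. With the mural marker score (pericytes and smooth muscle) as a covariate 239 genes passed, and likewise 239 with the astrocyte score. Each score shares information with age (exact permutation p = 0.0325 for both, before adjustment).

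**Figure D2:**
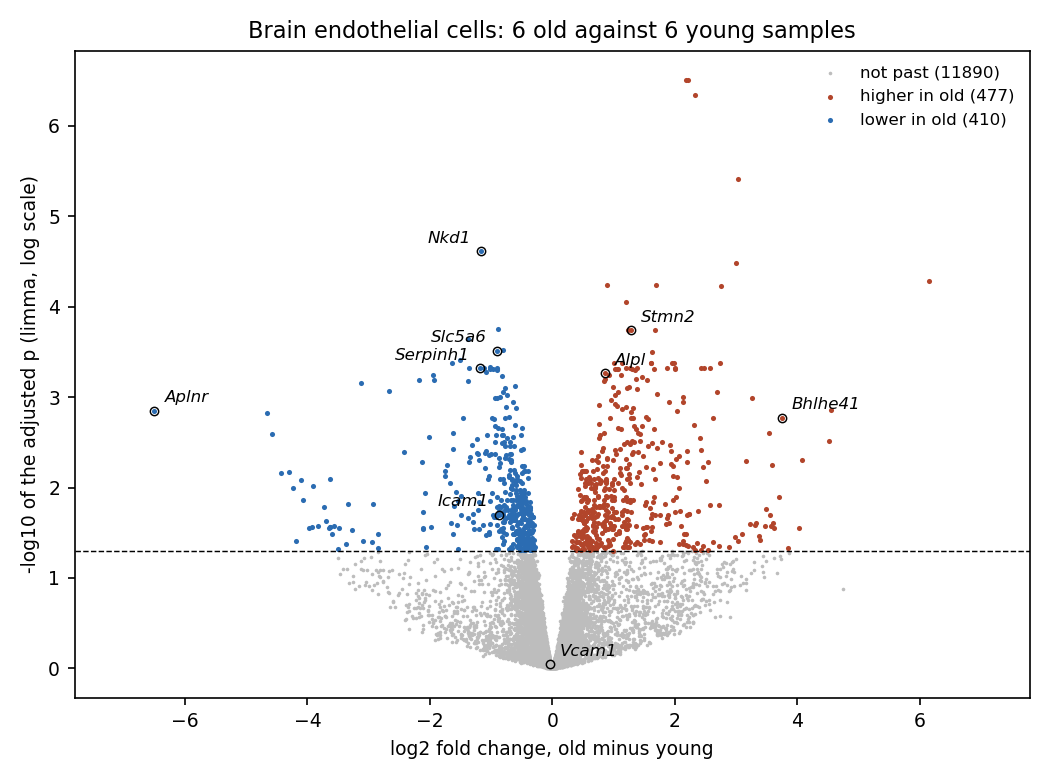
Log2 fold change between old and young samples (horizontal axis) against -log10 of limma's adjusted p (vertical axis, a log scale) for 12777 genes. The dashed line marks an adjusted p of 0.05, above which lie 477 genes higher and 410 lower in old samples, and Vcam1 sits near the origin.

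Large rises were seen in genes of low level in young samples. Tmem30b, a subunit of lipid flippases, went from 2.3 ± 3.38 to 51.7 ± 15.4 normalized counts (SD, n = 6 each, log2 fold 4.55, adjusted p = 0.0014), and was higher in every old sample than in any young one. The keratin Krt18 (4.52), Zkscan2 (4.08), the clock repressor Bhlhe41 (3.75) and Mogat1 (3.71) also rose with no overlap between the ages. Cyp4f14 (4.03), the urea transporter Slc14a1 (3.84), Serpina1d (3.63) and Prss12 (3.61) rose as well. Of these last 4, the first 3 did not pass with edgeR (adjusted p = 0.205, 0.418 and 0.076) and Prss12 was not tested there. By edgeR the log2 fold of Cyp4f14 was smaller, and that of Slc14a1 was 1.55. Slc14a1 reached 258 and Cyp4f14 115 in young 9, against at most 25 in the other young samples. Young 9 also had the highest astrocyte score of the young samples (10.96). Slc14a1 was highest of all in old 3 (357), which had the highest astrocyte score of all (11.30). Over the settings the log2 folds of Slc14a1 and Cyp4f14 went as low as 0.75 and 1.16. Whether RNA of astrocytes accounts for these rises was not settled. Serpina1d belongs to a family of near-identical genes, between which reads may have been split.

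Aplnr, the receptor for apelin and a marker of venous endothelium and vessel sprouts, fell from 678 ± 166 to 28.1 ± 39.1 (adjusted p = 0.00142), again without overlap. Its log2 fold was -6.50 as a difference of mean logs and -4.62 by edgeR, which placed Itga8 (-5.88) and Slc9a4 (-5.55) lower. The sodium-proton exchanger Slc9a4 (log2 fold -4.67), the integrin Itga8 (-4.57), the matrix protein Tgfbi (-4.24) and the matrix proteoglycan Ogn (-4.10) fell with no overlap, though edgeR did not test Tgfbi. Itga8 had 3 reads over the 6 old samples against 195 over the young, a ratio of 70.8 (95% counting interval 23.9 to 346), and Tgfbi 2 against 191, a ratio of 104 (28.4 to 865). The channel subunit Kcnmb1 (-4.42), Nlrc3 (-4.30), the calcium buffer Casq2 (-4.19), Gsg2 (-4.08) and the scavenger receptor Colec12 (-3.98) passed in limma but not in edgeR (adjusted p from 0.0542 to 0.242), where the log2 folds of Casq2 and Colec12 were -2.25 and -2.37. Kcnmb1 and Casq2 are known from muscle cells, whose other markers were also lower in old samples. Colec12 was highest in old 3 (225) and young 4 (568), the samples with the highest pericyte marker score of their age (8.94 and 9.73). Whether these falls are endothelial or come from RNA of mural cells was not settled.

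Transporters of the blood-brain barrier were lower in old samples. Of 34 tested genes on that list 0 rose and 12 fell, or 18 adjusted over the list alone, with a median log2 fold of -0.38 (camera adjusted p = 2.46e-09, and adjusted p = 0.0334 with an estimated correlation). Slco2b1, an organic anion carrier, fell from 27196 ± 3140 to 14579 ± 4140 (log2 fold -0.94, adjusted p = 0.00313), the biotin and pantothenate carrier Slc5a6 by 0.90 and the zinc and manganese carrier Slc39a8 by 0.83 on the log2 scale, each with no overlap between the ages. Genes that mark capillaries were lower as well, with 0 risen and 3 fallen of 15 (8 adjusted over the list alone), a median of -0.45, and an adjusted p of 0.000353, or adjusted p = 0.0298 with an estimated correlation. They were the actin-binding Ivns1abp (-1.23), the lipid carrier Mfsd2a (-0.76) and the transferrin receptor Tfrc (-0.81), of which Mfsd2a and Tfrc are also on the transporter list.

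Among junction genes only a few passed. In the tight and adherens junction list 0 rose and 3 fell of 17 (5 adjusted over the list alone): VE-cadherin Cdh5 (log2 fold -0.36), occludin Ocln (-0.33) and Cgnl1 (-0.58, edgeR adjusted p = 0.0501). Of 36 settings 21 ended the call on Ocln and 18 that on Cgnl1, in both cases including removal of the 3 samples with a GC trend (log2 folds -0.28 and -0.43, adjusted p = 0.073 and 0.0677), while with a term for those samples both passed (adjusted p = 0.0152 and 0.0134). The list's adjusted p of 0.00127 was lost with an estimated correlation (adjusted p = 0.141) and under quantile normalization (0.0742). Targets and components of Wnt and beta-catenin signalling, the pathway that maintains barrier properties, gave 0 risen and 3 fallen of 26, the same adjusted over the list alone. Nkd1, a feedback inhibitor of the pathway, fell from 14480 ± 1942 to 6447 ± 603 (log2 fold -1.16, adjusted p = 2.42e-05), Apcdd1 by 0.69 and Foxf2 by 0.39 on the log2 scale. The list passed (0.0181) but not with an estimated correlation (adjusted p = 0.45), and was lost in 5 settings: the astrocyte (0.151) and mural (0.0816) covariates, quantile normalization (0.189), the GC and length trend removed (0.072) and the 3 samples with a GC trend left out (0.0801). Pan-endothelial genes gave 1 risen (Clec14a, 0.51) and 1 fallen (Cdh5) of 26, or 2 and 4 adjusted over the list alone, a median of -0.21 and an adjusted p of 0.0257, lost with an estimated correlation (adjusted p = 0.393), with the astrocyte covariate (0.34), under quantile normalization (0.902) and without old 1 (0.0553). Venous genes gave 0 risen and 3 fallen of 20, also adjusted over the list alone, namely Aplnr, Icam1 and the amino acid carrier Slc38a5 (-0.69), and the list did not pass (0.0549), though it did in 12 of the settings, as low as 0.012 without old 9 and young 9.

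Arterial genes were higher in old samples, 8 risen and 0 fallen of 20 (13 and 1 adjusted over the list alone), with a median of 0.47 and an adjusted p of 8.23e-07, or adjusted p = 0.316 with an estimated correlation. The alkaline phosphatase Alpl rose from 39447 ± 6017 to 71248 ± 7870 (log2 fold 0.86, adjusted p = 0.000545) and Stmn2, which is also on the neuron list, from 3154 ± 289 to 7855 ± 2028 (1.28, adjusted p = 0.000181), both with no overlap. Clu, also an astrocyte marker, rose by 1.33. In the angiogenesis and tip cell list 3 rose and 5 fell of 38 (8 and 8 adjusted over the list alone, camera adjusted p = 0.354), with the vasodilator peptide Adm (1.37) and the growth factor Pgf (1.26) among the rises and Aplnr among the falls. Of 23 genes for coagulation and vessel tone 2 rose and 1 fell (4 and 2 adjusted over the list alone): the constrictor endothelin Edn1 (0.64) and angiotensin-converting enzyme Ace (0.57) were higher and the anticoagulant thrombomodulin Thbd (-0.94) was lower. That list's median was -0.13 and its mean 0.09, and it did not pass (0.853). Of 13 genes for caveolae and transcytosis 1 rose, Alpl, also adjusted over the list alone, and the list did not pass (0.493), with a median of 0.08 and a mean of -0.08.

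**Figure D3:**
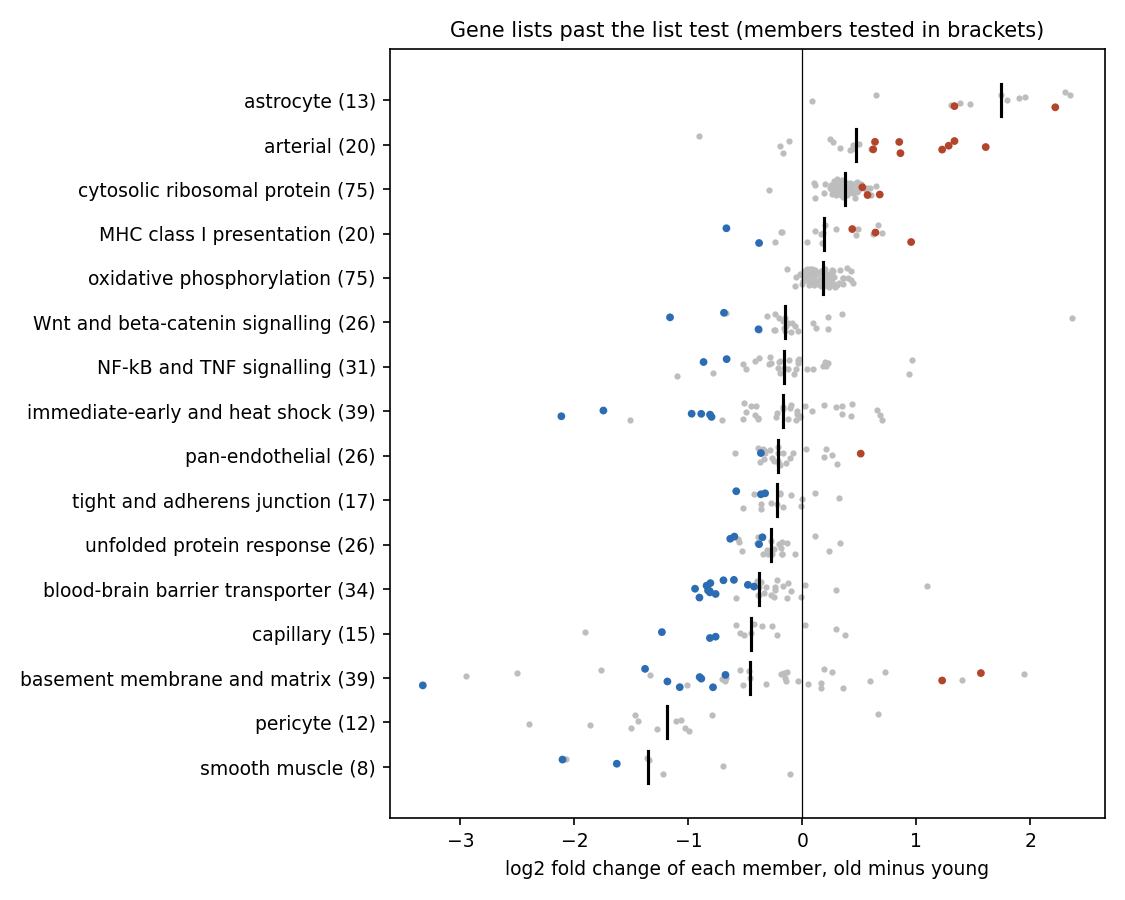
Log2 fold change between old and young samples (horizontal axis) of every tested member of the 16 lists past the camera test, 1 point per gene, with the list's median as a black bar. Coloured points passed the threshold over all genes, red for higher and blue for lower in old samples. Transporter genes have a median of -0.38 and arterial genes of 0.47.

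Genes of the basement membrane and matrix went both ways, with more falls than rises. Of 39, 2 rose and 8 fell (2 and 12 adjusted over the list alone), with a median of -0.46. Sparc, a secreted collagen-binding protein, fell from 111098 ± 13568 to 59489 ± 7198 (log2 fold -0.90, adjusted p = 0.00048), the collagen chaperone Serpinh1 by 1.18 and the collagen lysyl hydroxylase Plod1 by 0.89 on the log2 scale, each with no overlap. The list's adjusted p was 0.00178, lost with an estimated correlation (adjusted p = 0.393) and with the mural score as a covariate (0.0782). In the TGF-beta and BMP list 4 rose and 1 fell of 31 (5 and 1 adjusted over the list alone), among them the receptor Bmpr1a (2.24), the ligand Bmp6 (0.95) and the fallen Tgfbi, and the list did not pass (0.853). Among 10 fibroblast and meningeal markers Mgp, an inhibitor of calcification that is also on the arterial list, rose by 1.23 and Ogn fell, with 2 risen and 1 fallen adjusted over the list alone. That list had a median of 0.16 and a mean of -0.66, and did not pass (0.853).

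Several heat shock genes were lower in old samples. The list of immediate-early and heat shock genes gave 0 risen and 6 fallen of 39 (1 and 9 adjusted over the list alone), led by Hsp90ab1, which fell from 102703 ± 7814 to 53054 ± 9980 (log2 fold -0.97, adjusted p = 0.000483), Hspb1 (-0.89) and Hsph1 (-1.75). All 6 were among the 11 heat shock genes, whose median was -0.81, while 0 of the 28 immediate-early genes passed, with a median of -0.05. This division of the list was made after its values were seen. The list's adjusted p of 0.00427 was lost with an estimated correlation (adjusted p = 0.393) and with the astrocyte covariate (0.877). In the unfolded protein response 0 rose and 4 fell of 26 (7 adjusted over the list alone), with an adjusted p of 9.77e-05, and adjusted p = 0.0248 with an estimated correlation. The endoplasmic reticulum chaperone Hspa5 fell by 0.60, asparagine synthetase Asns by 0.63 and Dnajb11 by 0.35 on the log2 scale.

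Cytosolic ribosomal protein genes lay above 0 in 74 of 75 cases, with a median of 0.37. Rpl3 (0.53), Rps28 (0.68) and Rpl12 (0.57) rose and 0 fell, or 10 rose and 1 fell adjusted over the list alone. Without the 3 samples with a GC trend none of these 3 calls held, at log2 folds of 0.46, 0.63 and 0.58 (adjusted p = 0.0968, 0.106 and 0.0807), and that on Rpl12 ended in 21 of 36 settings. Members of this list moved together between samples (estimated correlation 0.74), and its adjusted p of 2.05e-14 became adjusted p = 0.49 with that correlation. Many of these genes have processed pseudogenes that could share their reads. Oxidative phosphorylation genes had 0 of 75 past the threshold in limma, also adjusted over the list alone, and 0 in edgeR. Of the 75, 12 had an unadjusted p under 0.05, against 3043 of all 12777 genes tested, with Atp5g1 nearest (0.39, adjusted p = 0.0617). The 75 had a median of 0.18. The list's adjusted p of 1.03e-05 was lost with an estimated correlation (adjusted p = 0.568), when a GC and length trend was removed (0.524) and with the mural covariate (0.0973). Of 13 mitochondrially encoded genes 0 were in the table. Prdx6, a peroxidase, rose by 0.60 in the antioxidant list (edgeR adjusted p = 0.061; 1 of 26, and 0 adjusted over the list alone, camera adjusted p = 0.224). For lysosome and autophagy (32 genes, smallest p for Ctsz, 0.37), cholesterol synthesis (23, Hsd17b7, 0.56) and cell cycle (27, Pcna, 0.44), 0 genes passed in limma, also adjusted over the list alone, or in edgeR, with 4, 2 and 6 at an unadjusted p under 0.05, and no list did (camera adjusted p = 0.304, 0.304 and 0.69). Under quantile normalization the lysosome (0.00351) and antioxidant (0.013) lists did pass. The cell cycle list had a median of 0.03 and a mean of -0.31. Senescence genes went both ways, 2 risen and 3 fallen of 23 (3 and 4 adjusted over the list alone). Timp2, an inhibitor of metalloproteinases, rose by 1.57, whereas the survival factor Bcl2 (-0.77) and Serpine2 (-1.22) were lower, and the list (median -0.04, mean 0.12) did not pass (0.69).

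Inflammatory genes did not move as a block. Of 53 interferon response genes 2 rose, the same adjusted over the list alone, and 0 fell: Ifi27l2a from 331 ± 48.3 to 962 ± 537 (log2 fold 1.40, adjusted p = 0.00405) and Ifi27 by 0.47. The interferon list did not pass (0.354), but did under quantile normalization (0.0184) and with the title number as a block over the 10 samples that share one (0.0252). In NF-kB and TNF signalling 0 rose and 2 fell of 31, also adjusted over the list alone, Icam1 and Nfkb2 (-0.66). That list passed (0.0293), but not with an estimated correlation (adjusted p = 0.543), the astrocyte covariate (0.935) or the GC and length trend removed (0.0828). It was also lost with the title number as a block (0.225) and without old 7 (0.0769) or young 5 (0.12). Among 20 genes for MHC class I presentation 3 rose and 2 fell (7 and 2 adjusted over the list alone). H2-K1 (0.64) and H2-Q4 (0.95) were higher and H2-T24 (-0.67) was lower. The list's adjusted p of 0.0364 was lost with an estimated correlation (adjusted p = 0.568) and in 10 settings. Among these were the mural covariate (0.632), the GC and length trend removed (0.0904) and the removal of old 2 (0.0644), old 9 (0.153), young 1 (0.119) or young 2 (0.0505) alone, so the call depended on single samples. These H2 genes are close copies of each other, between which reads may have been split.

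Among lists of markers of other cell types, those of astrocytes, smooth muscle and pericytes passed camera at the preset correlation but not at an estimated correlation. Astrocyte markers were above 0 in 13 of 13 cases with a median log2 fold of 1.74. Over all genes Clu and Aldoc (2.22) rose, and adjusted over the list alone 10 did. Aldoc did not pass in edgeR (log2 fold 1.46, adjusted p = 0.222) and lost its call in 20 of 36 settings. The adjusted p of the astrocyte list, 1.77e-06, became adjusted p = 0.393 with an estimated correlation, since the members moved together (0.73). The mean astrocyte score was 10.3 ± 0.75 in old and 8.71 ± 1.23 in young samples (exact permutation p = 0.0325, adjusted p = 0.103 over the 35 lists) and young 9 lay above the old mean. Smooth muscle markers were lower, 0 risen and 2 fallen of 8 (7 adjusted over the list alone), Myh11 (-2.10) and Acta2 (-1.63), with camera adjusted p = 0.000422 and adjusted p = 0.393 with an estimated correlation. Myh11 did not pass in edgeR (adjusted p = 0.0872), and each of the 2 genes lost its call in 15 of 36 settings, including without the 3 samples (log2 folds -1.36 and -1.14, adjusted p = 0.136 and 0.162). The smooth muscle score was 7.20 ± 0.878 against 8.51 ± 0.511 (exact permutation p = 0.0108, adjusted p = 0.0473). Of 12 pericyte markers 0 passed in limma or edgeR and 5 had an unadjusted p under 0.05 (1 rose and 3 fell adjusted over the list alone), with Notch3 nearest (-1.51, adjusted p = 0.0624), a median of -1.19 and camera adjusted p = 0.00721, or adjusted p = 0.543 with an estimated correlation. Without the 3 samples the pericyte list did not pass (0.0734).

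Microglial markers, the other cell type of the series title, gave 0 of 13 past the threshold in limma, also adjusted over the list alone, 0 in edgeR and 1 at an unadjusted p under 0.05 (camera adjusted p = 0.587, and 0.016 with the mural covariate). In sorted endothelial cells these markers measure only microglial RNA carried into the samples. Their mean score was low, 4.12 ± 1.72 in old and 3.96 ± 0.71 in young samples on the log2 scale, so they say nothing on microglia themselves. Adjusted over the list alone or over all genes, 0 of 9 oligodendrocyte markers (Enpp2, 0.20), 0 of 6 ependymal and choroid plexus markers (Ttr, 4.75, adjusted p = 0.133) and 0 of 5 platelet markers (Ppbp, 0.46) passed in limma or edgeR, with 0, 2 and 0 at an unadjusted p under 0.05. Their lists did not pass either (camera adjusted p = 0.853, 0.14 and 0.652). The ependymal result depended on single samples: its list passed as higher without young 9 (0.0271) or old 7 (0.0185) and in 8 settings in all, down to 0.000196 without the 3 samples, where Ttr had a log2 fold of 8.15 (adjusted p = 0.00088). The oligodendrocyte list had a median of 0.07 and a mean of -0.09. Of 5 oligodendrocyte precursor markers 0 passed in limma or edgeR, 2 had an unadjusted p under 0.05 and 2 rose adjusted over the list alone, Cspg5 being nearest (2.28, adjusted p = 0.0505), and of 7 neuronal markers 1, Stmn2, rose by either count. Both lists gave a camera adjusted p of 0.304, and the precursor list passed with the mural covariate (0.0092). Lists with fewer than 5 tested genes were not tested as lists. Their members of smallest p were the macrophage receptor Cd163 (-1.38, adjusted p = 0.265), the haem synthesis enzyme Alas2 (-1.21, adjusted p = 0.404), the Y-linked Kdm5d (-0.37, adjusted p = 0.398) and Laptm5, a lysosomal protein of leukocytes, which rose (0.84, adjusted p = 0.0162). Lists past the camera test numbered 16 (5 higher, 11 lower), of which 3 held with an estimated correlation: transporter, capillary and unfolded protein response. These 3, with the arterial and ribosomal lists, passed camera at the preset correlation in every setting that tested them. Fry does not set a list against other genes. It passed the same 3 and the arterial (adjusted p = 0.0105), junction (0.00119), Wnt (0.03), matrix (0.0389), pan-endothelial (0.0245) and smooth muscle (0.0405) lists. By fry the ribosomal (0.11), oxidative phosphorylation (0.229), heat shock (0.0523), NF-kB (0.124), MHC class I (0.24), astrocyte (0.0606) and pericyte (0.174) lists did not pass.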

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

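For each named gene, list score and sample measure, the sample farthest from the rest of its age was compared with the spread of the 6 samples by Dixon's ratio (gap over range). This passed in 22 of 254 groups of 6, where chance alone gives about 12.7, and 5 of the 22 were in young 9. The tests were not independent of each other, and no explanation was tested for these values.

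Among the young samples, young 9 was highest for Ttr, a choroid plexus gene, at 907 normalized counts against 0 to 4.6 in the others (ratio 0.747), for the ependymal and choroid plexus score at 7.65 against 3.48 to 4.24 (0.819) and for Hspa5 (41978 against 29346 to 32796, ratio 0.69), and lowest for Plod1 (8659 against 10943 to 12235, ratio 0.677). Young 1 was highest for Slc5a6 (2610 against 1922 to 2061, ratio 0.772) and Edn1 (8408 against 6501 to 7090, ratio 0.662). Young 2 was lowest for the caveola score (12.5 against 12.7 to 12.8, ratio 0.777) and the angiogenesis score (10.8 against 11.1 to 11.2, ratio 0.728). Rps28 was highest in young 3 (843 against 421 to 541, ratio 0.638), Stmn2 lowest in young 4 (2602 against 3089 to 3349, ratio 0.679) and Prss12 highest in young 5 (12.1 against 0 to 1, ratio 0.731).

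Among the old samples, Bmp6 was lowest in old 3 (142 against 272 to 317, ratio 0.807), Ocln in old 2 (20027 against 21848 to 22735, ratio 0.686), Slc39a8 in old 7 (2853 against 4431 to 5337, ratio 0.703) and the haem synthesis gene Alas2 in old 4 (70.9 against 1792 to 9108, ratio 0.664). Old 9 was lowest for Kdm5d (123 against 281 to 395, ratio 0.708) and for the TGF-beta and BMP score (10.4 against 10.8 to 10.9, ratio 0.721). In some genes a single sample held a few reads and the other 5 of its age were listed at 0, which gives a ratio of 1 by construction: Itga8 (2.6), Slc9a4 (3.5) and Tgfbi (1.8) in old 1, and Krt18 (8.6) in young 9.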

How the results depend on the processing

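The settings for the 3 and the 2 samples with a GC trend, the GC and length correction and the astrocyte covariate were chosen after seeing the data, the others before. Over 36 settings, 0 genes shared with the comparison as reported changed direction among the calls. Against 887 genes (477 higher, 410 lower in old), sample weights gave 1380 (765 higher) and DESeq2 1408 (747 and 661), a tool that also made more false calls on simulated reads. A 2-fold threshold left 350 (250 and 100) by construction. The mural covariate gave 239 (160 and 79) and the astrocyte covariate 239 (148 and 91), of which 214 and 229 were among the 887; each score shares information with age (exact permutation p = 0.0325 for both, unadjusted), and the cause was not tested further. The exact Wilcoxon test called 0 genes, 0 higher and 0 lower, with 2596 at an unadjusted p under 0.05. Its smallest p of 0.00216, shared by many genes, adjusts to 0.0505, so the step size of the ranks sets this count. Leaving out each sample in turn gave 554 to 1227 genes, 310 to 698 higher and 244 to 529 lower, lowest without young 4 and highest without young 9.

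A term for the 3 samples gave 1144 genes (866 shared) and their removal 904 (623 shared); for the 2 samples these were 1230 (887 shared) and 1081 (738 shared). Other scalings, pseudocounts, filters and variance models gave 733 to 951 genes. The median-of-ratios scaling repeats the authors' own factors, so it could move nothing. The share of calls that were higher, 53.8%, moved past 10 percentage points only with the fold threshold (71.4%) and the mural covariate (66.9%). Title numbers gave no sign of paired samples: same-numbered old and young samples had correlations of deviations of 0.0983, -0.018, -0.16, -0.136 and -0.0445, and 1 of 10 such samples correlated best with its own number. With the title number as a replicate block over those 10 samples 610 genes passed, 299 of them higher and 311 lower, a setting that also leaves out old 7 and young 5.

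Of the 72 named genes past the threshold, 18 stayed past in every setting except the Wilcoxon test and the fold threshold, and 36 when the 2 covariates are also set aside, each of which ended 45 calls. Calls that ended in at least 15 settings, beside those in the report, were Slc14a1 (21), Casq2 (20), Prdx6 (18), Dnajb11 (17), Rps28 (17), Ace (15) and Cyp4f14 (15). Sign changes between 2 values that both missed the threshold, 9 in all, were not counted as reversals. Vcam1 stayed between -0.16 and 0.15 in log2 fold (adjusted p from 0.536 to 0.996). The first component differed in mean between the ages in all 22 settings that gave it (exact permutation p from 0.00216 to 0.0108), with overlap at young 9 as reported. Lists higher in old, 5 as reported, numbered 8 with quantile normalization and 3 with the GC and length trend removed. The oligodendrocyte list, not past before, passed as lower with the astrocyte covariate (0.0111, over a range from 0.0111 to 0.991), and the pericyte list turned to higher without passing under the mural covariate (0.257), which contains its own genes. The cause of these list changes was not tested. Depth limits the genes of lowest level: the fold of a gene with few reads in an age depends on the pseudocount.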

Other observations

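Genes of the circadian clock stood out beyond the lists fixed beforehand, and were picked after their values were seen. Of 17 clock genes tested 9 rose and 2 fell in old samples. Nr1d1, a repressor in the clock's feedback loop, went from 2167 ± 256 to 10209 ± 2250 normalized counts (SD, n = 6 each, log2 fold 2.22, adjusted p = 3.13e-07) and Dbp, a clock-driven transcription factor, from 92.4 ± 31.5 to 744 ± 160 (3.03, adjusted p = 3.9e-06). Tef (1.12), Hlf (1.00), Nr1d2 (1.29), Per3 (1.36), Ciart (2.32), Bhlhe40 (0.75) and Bhlhe41 (3.75) rose too, while Arntl (-0.65) and Cry1 (-0.95), which peak at other hours, fell. Per1 (0.03), Per2 (-0.04), Cry2 (0.44), Clock (-0.35), Npas2 (0.78) and Nfil3 (-0.60) did not pass. The RNA-binding proteins Rbm3 (1.39, adjusted p = 0.00048) and Cirbp (1.67, adjusted p = 0.000483), both known to rise when cells are cooled, were higher in old samples, where heat shock genes were lower.

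Other genes of small p, also picked after their values were seen, were Flot2, a membrane raft protein (525 ± 100 to 2368 ± 314, log2 fold 2.18, adjusted p = 3.13e-07), Rasgrf2, an exchange factor for Ras (409 ± 46.9 to 2091 ± 500, 2.33, adjusted p = 4.59e-07), and Cyp26b1, which degrades retinoic acid (46 ± 12.2 to 392 ± 190, 3.00, adjusted p = 3.31e-05).

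All tests of explanations below were chosen after the patterns were seen, except the count of other splits of the samples. The rule for reading correlations within ages was reworded once after its results were seen, which left both of its outcomes as they were. Among 100 of the 462 ways to divide the 12 samples into 6 and 6, only 1, the real one, gave as many as 887 genes past the threshold. The highest other split gave 23, so chance division can be excluded for that count. For the 16 lists past camera, 3 of the 100 splits, the real one included, gave as many, the highest other giving 17. That share lies under 0.05, but other splits gave 17 and 16 lists with 0 genes past the threshold. Every other split drawn put at least 1 list past camera. A camera p at the preset correlation therefore does not by itself exclude chance for a list.

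Astrocyte markers tended higher and mural markers lower in old samples, by list calls that were lost with an estimated correlation (adjusted p = 0.393 for astrocyte and smooth muscle, 0.543 for pericyte) and an astrocyte score with adjusted p = 0.103. A lower share of endothelial cells, with all other cell types gaining alike, would raise both. The data argue against that form only: the astrocyte score differed by 1.58 and the smooth muscle score by -1.32 (old minus young). The astrocyte score minus the smooth muscle score differed by 2.89 (exact permutation p = 0.00433), which follows from the pattern itself and adds no evidence. A lower share through astrocytes alone is not excluded. The pan-endothelial score differed by -0.15 (exact permutation p = 0.00866, adjusted p = 0.0433 over the 35 lists). RNA of astrocytes carried into the sorted samples may account for the astrocyte part. Within ages, the 13 astrocyte markers had a mean pairwise correlation of 0.73, where 10000 random lists of matched level had a 95th percentile of 0.08, and young 9 carried them at the old level. Such joint movement was not particular to astrocytes. Smooth muscle markers had 0.507 (95th percentile 0.143) and pericyte markers 0.569 (95th percentile 0.1), and the cause of the mural part was not tested. Whether ageing itself changes how astrocytes adhere to vessels was not tested and stays open.

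The clock difference may come from a different hour of collection for the 2 ages, or from age. The labels give no hour, and a dissociation step of another length or temperature was not tested. Clock targets minus genes of the opposite phase separated the ages completely, with a gap of 0.886 on the log2 scale between the lowest old and the highest young sample. These genes were picked after their values were seen, so the gap decides nothing. Of the opposite phase, Npas2 lay higher in old samples (0.78, adjusted p = 0.0603), and the targets Per1 (0.03) and Per2 (-0.04) did not differ. With no hour in the labels, hour and age cannot be told apart here. The same holds for any other gene that varies with the hour. Whether an hour difference also enters the other age calls, those on heat shock genes among them, was not tested. Astrocyte RNA is argued against as the whole cause: with the astrocyte score as a covariate, 7 of the 11 clock genes called stayed past the threshold, Nr1d1 at a log2 fold of 2.16 and Dbp at 2.81. Calls on Hlf, Bhlhe41, Arntl and Cry1 ended with that covariate, with log2 folds of 1.04, 2.73, -0.76 and -0.62 against 1.00, 3.75, -0.65 and -0.95 without it.

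Transporter and capillary genes were lower in old samples, and arterial genes higher by a call lost with an estimated correlation (adjusted p = 0.316, against 0.0334 and 0.0298 for the other two). Dilution of endothelial RNA by other cells would lower all of them alike. It is argued against as the whole cause for transporter genes, whose score differed by -0.23 relative to the pan-endothelial score (exact permutation p = 0.00433). The arterial score was higher by 0.663 relative to it (exact permutation p = 0.00433), which the pattern itself implied. The arterial list also holds Clu, Stmn2 and Mgp, of the astrocyte, neuron and fibroblast lists. RNA of other cells could raise that score, so the arterial part decides nothing on dilution. A trend with GC content or transcript length is argued against as the whole cause, since with it removed, the listed genes kept out of the fit, the arterial score still differed by 0.437 (exact permutation p = 0.0173) and the transporter score by -0.40 (exact permutation p = 0.00216). A shift in the mix of vessel segments sorted is a candidate explanation for the arterial part. Its genes had a mean pairwise correlation of 0.296 within ages, against a 95th percentile of 0.094 in random lists. The GC and length trend was not removed for that correlation, and Clu, Stmn2 and Mgp were among its genes. It therefore cannot tell a shift of segments from RNA of other cells or from such a trend. For transporter genes the mean pairwise correlation (0.078) lay at the 75.4th percentile of random lists. For capillary genes (-0.006) it lay at the 10.8th, below the random median of 0.0657, so they gave no sign of a shift of segments. A mix constant within each age would give none either, and the cause stays open.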
